A study of Gallus gallus with 10 samples.

How the data were processed

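Nuclei were taken from 5 groups of chicken skin tissue with 2 ATAC-seq libraries each, each made from a fixed number of nuclei per the labels. Per the submitters' processing notes, BWA 0.7.17, MACS2 and Partek were used with the builds GRCg6a and galGal6, and their settings are not stated there. The deposited peak files hold 1 list of MACS2 peaks per library. In the deposited peak files the score is 10 times the -log10 q value cut to a whole number. The fold enrichment in the deposited peak files is a ratio of the summit pileup to the local background, and 2 further columns give the -log10 p and -log10 q of each summit, as the values show. The smallest -log10 q in each deposited file lay near 1.3, a q value of 0.05. Positions in the deposited files, with starts counted from 0 in peak and region lists, are in bp. The authors' deposited lists of regions specific to an E9 site hold positions alone, and the test behind them is not stated. The authors' deposited gene models are those of Ensembl for GRCg6a with the duplicated sequence inserted in HOXC10 on chromosome 33 (24356 gene models, 16779 of them protein-coding, 4344 of these without a symbol).

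A peak interval listed with several summits was counted once. Peak files hold no read counts, so the total depth is unknown and no count model was fitted. The local background was recovered for a part of the summits by solving their fold and Poisson p, which matched the -log10 p within 0.002 for 99.9 to 100% of the summits tried. The lowest background among the matched summits of a library was taken as its background. Dividing this lowest value by the shortest peak, taken as the fragment length, gave tags per kb as a relative measure of depth. In coordinate frame, the E9 peaks and the authors' lists follow plain GRCg6a and the juvenile peaks follow the sequence with the insertion. Past the insertion, 107 pairs of E9 and juvenile summits lay its length apart and 18 at the same position (tolerance 40 bp), and before it 188 and 804. Positions were not shifted, and overlaps between E9 and juvenile regions left out chromosome 33 past the insertion start.

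Peaks of the 6 E9 libraries were merged into 111355 regions and those of the 4 juvenile libraries into 74891. A region was open in a library when a peak overlapped it by 1 bp or more. It was called for a group when open in both its libraries and in neither library of the other group. The counts were set beside the crossed splits, in which each side holds 1 library of each group. Regions were assigned to the nearest transcript start of a protein-coding gene within 100 kb, and promoters reached 1000 bp from a start. A total of 18 gene lists (HOX paralogs 1 to 4, 5 to 8 and 9 to 13, regulators of head, trunk and limb, feather dermal, fibroblast matrix, WNT, BMP, FGF and SHH and retinoic acid genes, and markers of epidermis, melanocytes, muscle, endothelium, blood, nerve and cartilage) were tested against 10000 random gene lists of the same size, matched in 10 bins of regions per gene. The test was two-sided, with Benjamini-Hochberg adjustment over 252 tests of 18 lists and 14 sets of regions. The random lists drew genes independently of their position. HOX genes are neighbours within clusters, so the p values of the HOX lists may be too small. The 54 list tests of regions closed only in 1 site were added and adjusted as a separate family, as were the added cluster sets and the added overlaps. Each HOX cluster was taken from its first to its last named HOX gene with 20 kb flanks. It was tested against 10000 windows of the same length at random gene starts, adjusted over the planned sets. The windows were not matched in number of regions, so a cluster dense in regions can hold more called regions for that reason. Genes with 5 or more regions were ranked by a one-sided hypergeometric test, which is exact, adjusted over genes. Regions of a gene are neighbours, so these p values rank genes and do not test replicates. Overlaps of juvenile regions with the authors' lists were tested by two-sided Fisher's exact test.

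Named genes were, per comparison and direction, up to 10 genes with a symbol and the lowest p past an adjusted 0.05, the HOX genes, and the 4 members with most called regions of each list that passed. Some genes that this rule names are not reported here. The comparisons, lists, this rule and most of the other settings were fixed before the data were examined. Genes named at their promoters outside the HOX clusters, and sets of regions closed only in 1 site, were chosen after the data were seen. The other settings were peaks with a -log10 q of 5 or more, equal numbers of peaks per library (61253 for E9 and 32002 for juvenile, the top by -log10 p), an overlap of at least 50% of the region or the peak, short windows around summits, regions within 50 kb or at least 1000 bp from a start, Fisher's exact test for lists, no cluster flanks, a replicate block, and each library left out in turn.

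The code was tested on simulated data. Interval overlaps differed from a direct count in 0 of 200 runs. Of 200 regions planted as open in scalp against tail, 82.5% were called. This share follows from the chances of opening per library that the simulation set, so it is not the sensitivity of the rule in real data. With regions drawn at random, 4.17% of 360 list tests had p under 0.05 and 0 genes passed in 20 runs. In E9 scalp against tail, lists enriched by 1.5 times reached an unadjusted p under 0.05 in 48.9% of 90 tests and by 2 times in 68.9%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Motif tests were planned and not run, since no genome sequence was used here, and the table of RefSeq symbols was not used. HOXB1 is annotated as a pseudogene and was left out of the tests. HOXC genes other than HOXC8, HOXC9 and HOXC10 are not named as protein-coding in the gene models. They are therefore missing from the HOX lists and promoter counts. RNA-seq and Micro-C data of the study were not analysed here.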

Results

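Open chromatin was profiled by ATAC-seq in chicken skin mesenchyme from 5 groups of 2 libraries each. At embryonic day 9 (E9) the groups were scalp, anterior dorsal (called back here) and tail dermis of White Leghorn embryos. In juvenile Polish chickens, a crested breed, they were the mesenchyme of the long crest feathers and that of the short cranial feathers beside them. Per the labels both juvenile tissues carry a short duplication, which the deposited gene models hold as an insertion in HOXC10. The questions were how dermis of different body sites differs in open chromatin, above all at the HOX genes that give body positions their identity, and how crest and cranial feather mesenchyme differ at the HOXC cluster.

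The E9 libraries held 61827 and 63843 peaks for scalp, 61253 and 65375 for back, and 61434 and 66974 for tail. The crest libraries held 56813 and 49215 peaks, and the cranial feather libraries 32002 and 35128. The share of peaks within 1000 bp of an annotated transcript start was 22.7 and 24.4% in crest and 34.5 and 32.5% in cranial feather, against 19.3 to 21.7% in the E9 libraries. Read counts are not in the peak files, so the total depth of each library is unknown. The density of background tags recovered from the peak statistics was 20.3 and 19.9 tags per kb in crest and 19.8 and 20.2 in cranial feather. In the E9 libraries it was lowest in back replicate 2, at 13.8, whose peaks were also the narrowest, with a median of 324 bp against 471 to 738 bp elsewhere. Libraries of the same group shared a median Jaccard index of 0.531 of their covered bases (range 0.470 to 0.567, 5 pairs). The median was 0.423 between E9 sites (0.329 to 0.488, 12 pairs), 0.385 between the juvenile tissues (0.344 to 0.445, 4 pairs) and 0.258 between E9 and juvenile libraries (0.207 to 0.334, 24 pairs). With 2 libraries against 2, the smallest two-sided permutation p is 0.333, so group differences in values per library are given with their spread and no p. Positions are on GRCg6a and counted from 1.

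Scalp and back dermis differed at HOX promoters. The promoters of HOXB4, HOXB5, HOXB7, HOXB9, HOXC9, HOXC10, HOXA2 and HOXA5, genes that pattern the body from hindbrain to trunk, were open in both back libraries and in neither scalp library. No promoter of a named HOX gene was open in both scalp libraries and closed in both back libraries. Of the 376 promoters of genes on the fixed lists, 31 were open in back only and 4 in scalp only, where crossed splits of the same 4 libraries gave 1 to 3. Those open in back only also included TBX5, a limb field regulator, MEOX1, a somite regulator, and the keratinocyte genes KRT14 and SFN. The back libraries had more open promoters of epidermal markers, 10 and 15 of 23, than scalp (6 and 7) or tail (6 and 8). Those open in scalp only were ALX1, a regulator of frontonasal mesenchyme, SPRY1, an inhibitor of FGF signalling, and the globin genes HBA1 and HBBA. The non-HOX promoters were chosen after their values were seen.

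Across the genome, 8871 of 111355 E9 regions were open in both scalp libraries and neither back library, and 6987 were open in back and not in scalp. The crossed splits gave 999 to 1311. The promoter share was 4.61% of the scalp regions and 11.2% of the back regions, against 14.4% of all E9 regions. In 4 genes the regions open in scalp only were concentrated past an adjusted p of 0.05 in an exact one-sided hypergeometric test over 6531 genes, with 306 genes at an unadjusted p under 0.05. CPZ (ENSGALG00000030209, chromosome 4, 81163250 to 81197855), a carboxypeptidase with a WNT-binding domain, had 10 of its 22 regions open in scalp only (adjusted exact p = 0.00778). DICER1, which processes microRNAs, had 7 of 12, the potassium channel gene KCNJ6 6 of 9 and the mitochondrial peptidase gene MIPEP 7 of 14. No gene passed for back (229 unadjusted). Counting only regions within 50 kb of a transcript start left 1 gene for scalp, and without scalp replicate 2 there were 16.

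Back and tail dermis differed at the promoters of 4 HOX genes. HOXA2, HOXB6, HOXC9 and HOXD4 were open in both back libraries and in neither tail library, and no promoter of a named HOX gene showed the opposite. Over the 376 list promoters, 22 were open in back only and 5 in tail only, and the crossed splits gave 1 to 6. The 5 open in tail only were ALDH1A1, an enzyme of retinoic acid synthesis, GREM1, a secreted BMP antagonist, SHH, a signalling ligand of feather buds, ALX1 and SPRY1. They were named after their values were seen.

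In all, 4364 regions were open in back and not in tail and 6377 in tail and not in back, beside 962 to 2024 in the crossed splits. Promoters made up 12.1% of the back regions and 4.53% of the tail regions. TRMT1L (chromosome 8, 11257067 to 11277947), a gene of the tRNA methyltransferase family, had 6 of its 13 regions open in back only (adjusted p = 0.0458, exact one-sided hypergeometric test), and it was the only gene that passed, with 191 at an unadjusted p under 0.05. Its call ended with regions counted within 50 kb, with equal numbers of peaks and without either tail library, each of which left 0 genes. No gene passed for tail (296 unadjusted).

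Scalp and tail dermis, the sites farthest apart along the body, differed at HOX genes of the B and C clusters. HOXB4, HOXB5, HOXB7 and HOXC10 were open at their promoters in both tail libraries and in neither scalp library. At HOXC10 the tail libraries had different peaks within 1000 bp of the start, 7585746 to 7586058 in replicate 1 and 7584690 to 7585219 in replicate 2. The region at its start (7585746 to 7586536) was therefore called over scalp for back and not for tail. Over the list promoters, 18 were open in tail only and 9 in scalp only, beside 1 to 6 in the crossed splits. The tail promoters, chosen after their values were seen, included GREM1, ALDH1A1, TBX5 and MEOX1, and the scalp promoters included EDAR, a receptor needed for feather placodes, LMX1B, a regulator of dorsal limb identity, and FGF3.

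The regions open in scalp and not in tail numbered 7859 and those in tail and not in scalp 8279, beside 842 to 1713 in the crossed splits. Scalp regions were concentrated in 10 genes (270 unadjusted), 9 of them with a symbol. CPZ again had 10 of 22 regions (adjusted exact p = 0.00418), MOCOS, a molybdenum cofactor enzyme, had 7 of 11, KCNJ6 6 of 9, RAPGEF4 7 of 15, TERF1 7 of 16, SLC9A9 8 of 22, DICER1 6 of 12, TMEM144 5 of 8 and PHAX 7 of 17. No gene passed for tail (287 unadjusted). Counting regions within 50 kb left 1 gene for scalp, and equal numbers of peaks left 4.

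**Figure D1:**
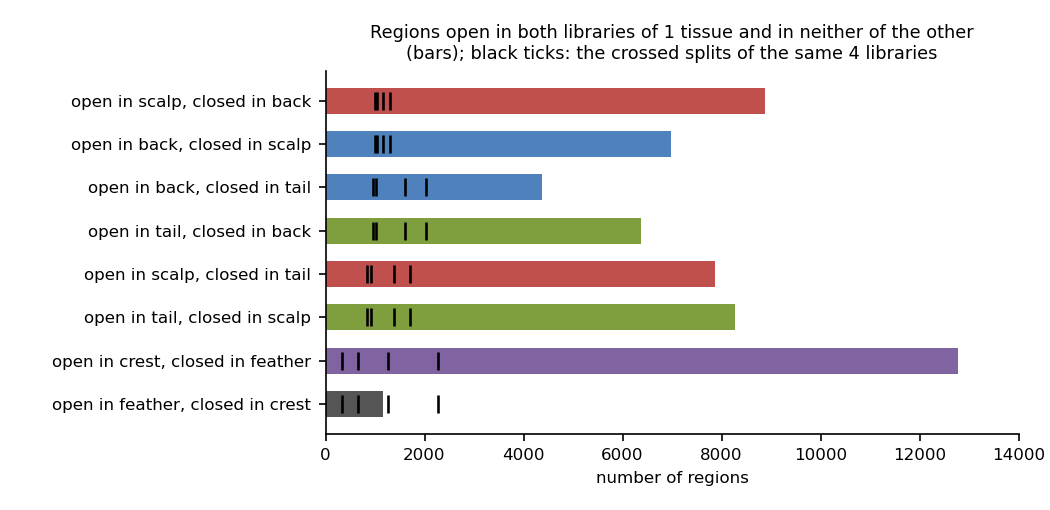
Bars give the number of regions open in both libraries of 1 tissue and in neither library of the other, and black ticks the crossed splits of the same 4 libraries. The E9 counts lie between 4364 and 8871 and above every crossed split, which reach at most 2024, while 1170 regions open in cranial feather only lie within the crossed range of 330 to 2273.

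Taking the 3 E9 sites together, scalp dermis had the most regions open in a single site and the most closed in a single site. Regions open in scalp and in none of the 4 other libraries numbered 5209, against 2430 for back and 3510 for tail. Regions closed in scalp and open in all 4 other libraries numbered 2806, against 1709 closed only in back and 1041 closed only in tail. The 12 pairs that mixed sites gave 386 to 859 regions open only in the pair and 203 to 754 closed only in it. An open call needs a peak in both libraries of a site, so the open counts rise with replicate agreement. Their order was also that of the Jaccard index between replicates, 0.567 in scalp, 0.535 in tail and 0.470 in back. Among list promoters, 12 were closed only in scalp, and these were HOXB4, HOXB5, HOXB7, HOXC10, EVX2, MEOX1, TBX5, SOX17, STRA6, BMPR1B, CXCL14 and NEFM. The HOXC10 promoter call rests on different peaks in the 2 tail libraries. Only 2 list promoters, ALX1 and SPRY1, were closed only in back, and 5 were closed only in tail, while mixed pairs gave 0 to 4. Back alone opened 10, among them HOXA2, HOXC9, the hedgehog ligand gene IHH and the pigment cell gene PMEL. Tail alone opened GREM1 and ALDH1A1, and scalp alone opened HBBA, counts within the 0 to 4 that mixed pairs opened. The promoters outside the HOX clusters were named after their values were seen, and the regions closed only in a site were counted after the data were seen.

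HOX paralogs 5 to 8 had 7 regions closed only in scalp against a mean of 0.911 in random gene lists (ratio 7.68, adjusted permutation p = 0.0216), with 2 each at HOXB6 and HOXB7 and 1 each at HOXA6, HOXB5 and HOXC8. The ratio was 6.02 (adjusted permutation p = 0.173) in regions at least 1000 bp from a transcript start, and 5.35 and 5.09 (adjusted p = 0.054 and 0.0864) without back replicate 1 or tail replicate 1. HOXB5, HOXB6 and HOXB7 are neighbours on chromosome 27, and the random lists did not keep neighbours together. The p values of this list may therefore be too small. The 2 other HOX lists did not pass in the set closed only in scalp, with a ratio of 4.01 for paralogs 1 to 4. No planned HOX list test between 2 E9 sites passed after adjustment. Regions open in back and not in scalp had ratios of 2.72, 2.99 and 2.13 for paralogs 1 to 4, 5 to 8 and 9 to 13. Paralogs 5 to 8 had a ratio of 3.63 in regions open in tail and not in scalp.

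At the level of single genes, CPZ had 8 of 22 regions open only in scalp (adjusted p = 0.0167, exact one-sided hypergeometric test) and TRMT1L 6 of 13 open only in back (adjusted exact p = 0.00145). Neither call remained when regions were counted within 50 kb. The summed counts over the 3 sites, 11149 regions open in a single site and 5556 closed in a single site, exceeded the highest of the 14 other ways to pair the 6 libraries, 6624 and 3768.

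The authors' deposited lists of differentially accessible regions specific to a site held 15165 regions for scalp, 8490 for back and 6536 for tail. The authors' deposited scalp list was rich in regions nearest to HOX genes of paralogs 1 to 8. A place on this list does not mean open in scalp. The HOXB window had 25 regions on it, yet 0 regions open in scalp and closed in back or in tail, and 9 closed only in scalp. In the HOXA window, with 17 on the list, 3 regions were open in scalp and not in back and 7 the other way. HOX paralogs 1 to 4, which pattern hindbrain and neck, had 22 E9 regions on it against a mean of 6.63 in random gene lists (ratio 3.32, adjusted permutation p = 0.0126), spread over 7 of 9 members, with 6 at HOXB3 and 4 each at HOXA3 and HOXB2. HOX paralogs 5 to 8, which pattern the trunk, had 17 against 3.86 (ratio 4.40, adjusted permutation p = 0.0126) over 8 of 9 members, with 4 at HOXA6, 3 at HOXB6 and 2 each at HOXA7, HOXB5, HOXB7 and HOXC8. The p of both tests was 0.0002, the smallest that 10000 random lists can give. Many members of these gene lists are neighbours, unlike the random genes, so both p values may be too small. HOX paralogs 9 to 13 had 12 against 7.83 on the authors' deposited scalp list (ratio 1.53, adjusted permutation p = 0.746). On the authors' deposited tail list, HOX paralogs 9 to 13, which pattern the posterior body, had 12 regions against 3.64 (ratio 3.29, adjusted permutation p = 0.0504), with 5 at HOXA11, and did not pass.

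These lists were not lists of open regions alone. On the authors' deposited scalp list, 3135 regions were open only in scalp and 1550 were closed only in scalp by their E9 peaks. The corresponding counts were 573 and 862 for the authors' deposited back list and 1325 and 243 for the tail list. The back libraries had peaks on 45.2 and 32.2% of the authors' deposited back list, fewer than the scalp libraries had on it (53.0 and 55.7%). AMY1A, an amylase gene on chromosome 8 (11450029 to 11467906), had 11 of its 19 regions on the authors' deposited back list (adjusted p = 2.85e-05, exact one-sided hypergeometric test). TRMT1L followed with 7 of 13, the gene CBWD1 with 6 of 10 and FLNA, which encodes an actin crosslinker, with 6 of 12. In all 8 genes passed for back, 2 without a symbol for tail and 0 for scalp (240 unadjusted). With regions counted within 50 kb, 0 genes passed for back.

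In E9 scalp the HOXC and HOXB windows held fewer peaks than in back or tail. The HOXC window (chromosome 33, 7565953 to 7636791, with 20 kb on each side of HOXC8 to HOXC10) held 5.5 ± 0.707 peaks per library in scalp, 22 ± 2.83 in back and 17.5 ± 0.707 in tail (SD, n = 2 each). Of its 5 protein-coding models these 3 HOXC genes alone have a symbol, so the window may not span the whole cluster. The HOXB window (chromosome 27, 6131929 to 6300220) held 11 ± 5.66 peaks in scalp, 37.5 ± 3.54 in back and 33.5 ± 2.12 in tail (SD, n = 2 each). HOXA (chromosome 2, 32557089 to 32702168) held 28.5 ± 0.707, 37.5 ± 3.54 and 30 ± 5.66, and HOXD (chromosome 7, 16242309 to 16347333) held 20.5 ± 2.12, 27.5 ± 7.78 and 22 ± 1.41, in the same order. In HOXA the peaks of the scalp libraries covered 15.4 and 14.8 kb, against 19.8 to 32.4 kb in the back and tail libraries. Differences between clusters were not tested.

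In the HOXC window 9 of 25 regions were open in back and not in scalp, where random windows of equal length had a mean of 0.658 (adjusted p = 0.0096, permutation of windows), and 7 were open in tail and not in scalp (mean 0.464, adjusted p = 0.0096). Over all E9 regions, 6.27% were open in back and not in scalp and 7.43% in tail and not in scalp. The random windows were not matched in number of regions, so the cluster p values may also reflect how dense in regions the clusters are. No HOXC region was open in scalp and closed in back or in tail. In HOXB, 15 of 59 regions were open in back and not in scalp (mean 1.59) and 13 in tail and not in scalp (mean 1.18), each with an adjusted p of 0.0096. The authors' deposited scalp list covered 25 HOXB regions (mean 2.29, adjusted permutation p = 0.0096), 12 HOXC regions (mean 0.932, adjusted p = 0.0096) and 17 HOXA regions (mean 1.95, adjusted p = 0.0126). The authors' deposited tail list covered 8 HOXC regions (mean 0.423, adjusted p = 0.0096) and 11 HOXA regions (mean 0.880, adjusted p = 0.0134), and the back list 10 HOXB regions (mean 1.45, adjusted p = 0.0193). HOXD passed in no set, with a lowest adjusted p of 0.0935. Regions closed only in scalp, counted after the data were seen, numbered 9 in HOXB (adjusted permutation p = 0.0036), 5 in HOXC (adjusted p = 0.0036) and 4 in HOXA (adjusted p = 0.0328). Without the flanks, the HOXA and HOXC counts closed only in scalp fell to 3 and 2 (adjusted permutation p = 0.0656 and 0.0576) and the tail list count in HOXC to 2 (adjusted p = 0.137), and the HOXB count of the back list fell to 5 with stricter peaks (adjusted p = 0.167).

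**Figure D2:**
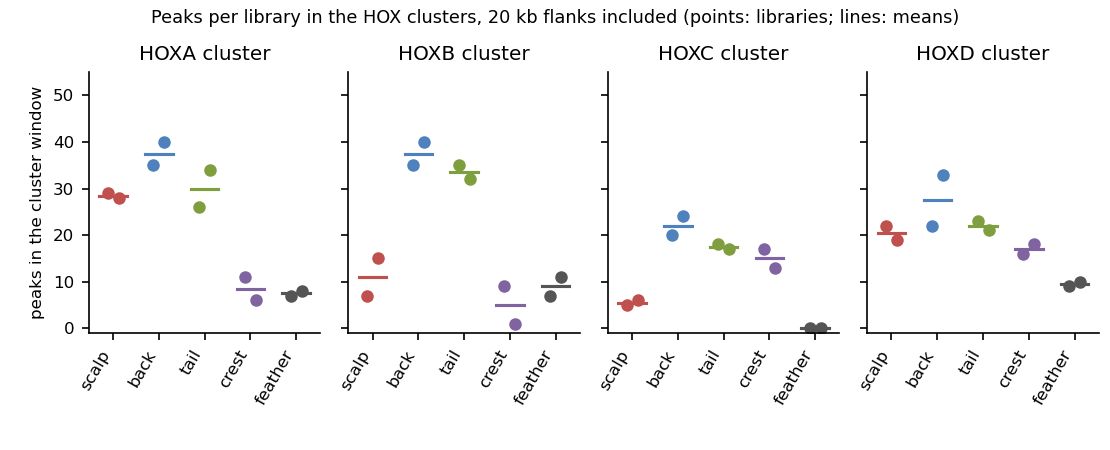
Points give the number of peaks per library in each HOX cluster with 20 kb flanks, and lines the mean of the 2 libraries of a group. In the HOXC panel scalp lies at 5 and 6 peaks, back at 20 and 24, tail at 18 and 17, crest at 17 and 13, and cranial feather at 0.

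Inside the HOXC window, the regions closed only in scalp were within HOXC8 downstream of its start (7606809 to 7609627), in an intron of HOXC10 (7589262 to 7590011), at the promoters of 2 unnamed gene models (7571950 to 7573748 and 7621878 to 7623424) and in an intron of the second of these (7631401 to 7632335). Back alone opened the HOXC9 promoter (7600893 to 7601559) and regions between genes at 7596626 to 7597308 and 7617603 to 7618619. Tail alone opened a region in an intron of HOXC8 (7613042 to 7613762). The E9 positions past the insertion in HOXC10, which begins at 7587783, are offset by its length from the gene models used, so these places are approximate by that much.

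**Figure D3:**
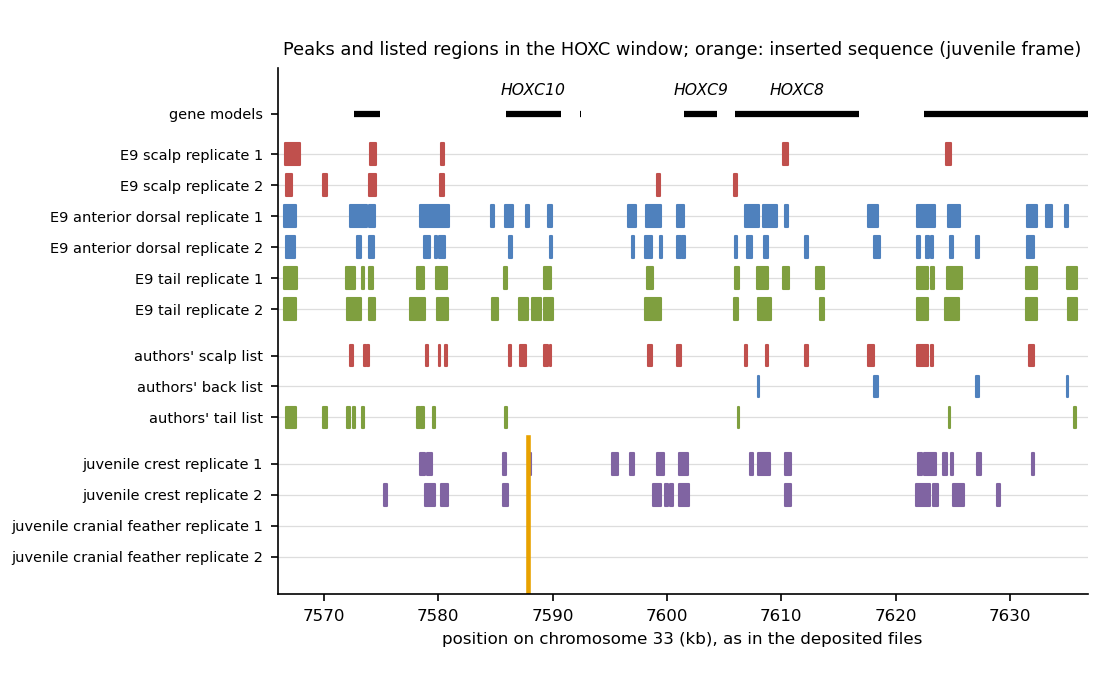
Each bar is a peak of 1 library or a region of the authors' deposited lists along chromosome 33, in kb, with gene models on top and the inserted sequence in orange. Scalp libraries hold 5 and 6 peaks, and the cranial feather libraries hold 0 where the crest libraries hold 17 and 13.

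Promoters of HOX genes were open most often in back dermis, as were those of the list genes in general. Of the promoters of list genes other than the epidermal markers, 79.6 and 79.3% were open in the back libraries, against 68.0 and 68.8% in scalp and 68.8 and 73.1% in tail. Of 9 genes of paralogs 1 to 4, the promoter was open in both libraries in 3 for scalp, 8 for back and 6 for tail. Of 9 genes of paralogs 5 to 8 the counts were 3, 8 and 4, and of 13 genes of paralogs 9 to 13 they were 4, 8 and 6. In the juvenile tissues the counts were 3 in crest and 3 in cranial feather for paralogs 1 to 4, 1 and 2 for paralogs 5 to 8, and 5 and 2 for paralogs 9 to 13. These promoter counts have no test across libraries, and the E9 calls at HOXC8 and HOXC9 are approximate, since both genes lie past the insertion.

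**Figure D4:**
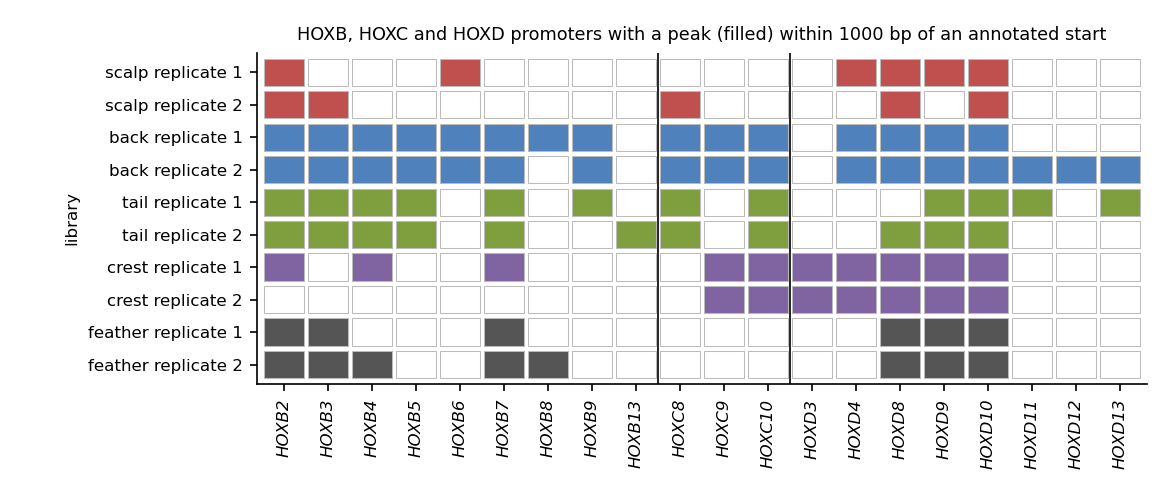
Filled squares mark a peak within 1000 bp of an annotated start of each named gene of the HOXB, HOXC and HOXD clusters (columns) in each library (rows). HOXC10 is filled in both back, both tail and both crest libraries, and in no scalp or cranial feather library.

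Crest and cranial feather mesenchyme grow long and short feathers on the same head. Their peaks differed at HOXC, at WNT pathway genes and at epidermal genes, and each of these calls ended in some settings. The promoters of HOXC9 and HOXC10 were open in both crest libraries and in neither cranial feather library, as were those of HOXD3 and HOXD4. HOXB3 was the single list gene whose promoter was open in cranial feather only, against 40 in crest only and 1 to 9 in the crossed splits. The cranial feather libraries held 32002 and 35128 peaks, against 56813 and 49215 in crest, and fewer open promoters in general. Of promoters of list genes other than the epidermal markers, 48.7 and 56.4% were open in cranial feather, against 69.7 and 62.9% in crest. The crest promoters included OTX1, a head patterning regulator, PAX3 and TWIST2, regulators of neural crest and dermis, the signalling genes SHH, WNT3A and WNT7B, the collagen matrix genes DCN, LUM and COL6A1, and the epidermal genes KRT5, KRT14, CDH1 and DSP. The non-HOX promoters were chosen after their values were seen.

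Of 74891 juvenile regions, 12785 were open in crest and not in cranial feather, and 1170 the other way. The crossed splits gave 330 to 2273, so the count for cranial feather did not exceed the spread between replicates. The cranial feather libraries held fewer peaks, and with 32002 peaks taken from each library the counts were 4901 for crest and 2702 for cranial feather, beside 439 to 1383 in the crossed splits. This excess did not hold in every setting. Without cranial feather replicate 1 or 2 the ratio of crest to cranial feather counts turned to 0.717 and 0.736, and without crest replicate 1 or 2 it was 2.08 and 2.40, so the tissue left with 1 library, which has the looser rule, had more each time. In the 4 pairs of 1 library against 1 it was 1.02 to 1.09, and equal numbers of peaks hold it near 1 by construction.

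WNT pathway genes had 131 regions open in crest only, against a mean of 70.8 in random gene lists (ratio 1.85, adjusted permutation p = 0.0126), over 30 of 39 members. WNT5A, a ligand of mesenchymal WNT signalling, had 13 of 27 regions, CTNNB1, which encodes beta-catenin, 10 of 22, and LEF1, FZD7, WNT3A and TCF7L2 had 8 each, of 18, 22, 15 and 39. Epidermal keratinocyte markers had 65 regions against 26.3 (ratio 2.47, adjusted permutation p = 0.0126), over 16 of 23 members, with 15 of 28 at TP63, the master regulator of stratified epithelia, 7 of 15 at EDAR, 6 of 13 at LAMA3 and 6 of 7 at DSP. The p of both lists was 0.0002, the smallest that the random lists can give. At equal numbers of peaks the WNT ratio was 1.84 (adjusted permutation p = 0.0806). The epidermal ratio was 2.09 (adjusted permutation p = 0.063) in regions at least 1000 bp from any transcript start and 1.65 (adjusted p = 0.0864) without crest replicate 2.

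No other fixed list passed. Cranial neural crest and frontonasal regulators had a ratio of 1.73 (82 against 47.5, adjusted permutation p = 0.0588), BMP and TGF-beta genes 1.49, retinoic acid genes 1.91 and FGF and SHH genes 1.43. Feather dermal condensation and dermal papilla genes stood at 1.20, dermal fibroblast matrix genes at 1.21 and trunk and limb field regulators at 1.17. The HOX lists stood at 1.39 for paralogs 1 to 4, 0.413 for 5 to 8 and 1.28 for 9 to 13. Markers of other cell types stood at 1.58 for melanocytes, 1.42 for Schwann cells and neurons, 1.05 for blood and immune cells, 0.909 for skeletal muscle, 0.719 for cartilage and bone, and 0.417 for endothelium. Over all 252 planned list tests, these and those of the E9 sets and the authors' lists, 4 passed and 26 had an unadjusted p under 0.05.

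**Figure D5:**
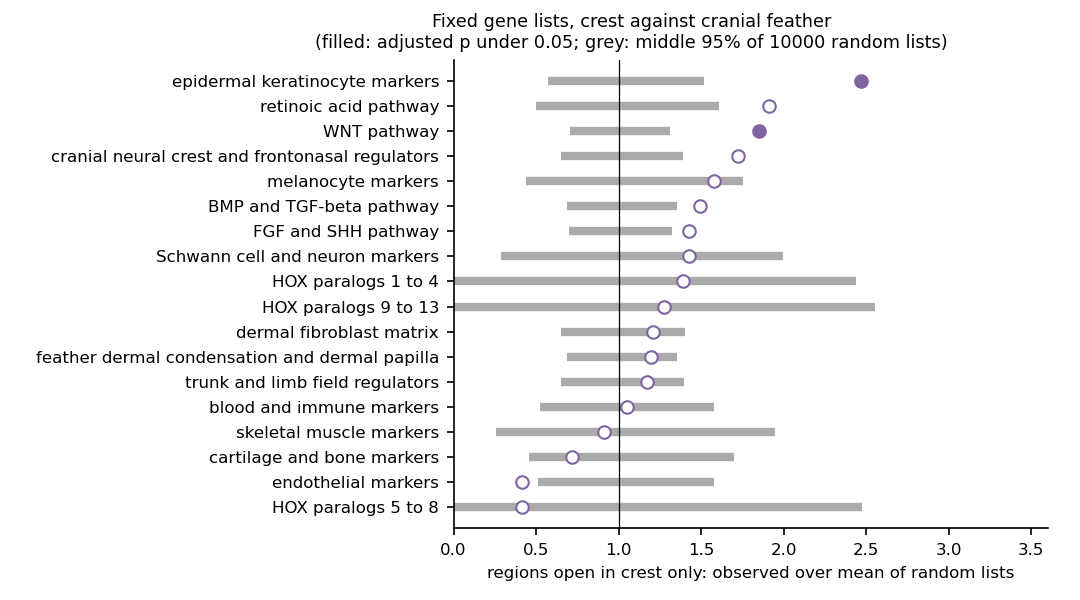
Circles give the number of regions open in crest only near the genes of each fixed list, divided by the mean of 10000 random gene lists, with the middle 95% of the random lists in grey and filled circles for an adjusted p under 0.05. The epidermal list lies at 2.47 and the WNT list at 1.85.

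At single genes, ranked by p, regions open in crest only had the lowest p at OTX1 (ENSGALG00000028817, chromosome 3, 9984822 to 9987580), with 15 of 24 regions (adjusted p = 0.0017, exact one-sided hypergeometric test). TXNRD3, a thioredoxin reductase gene, had 13 of 19, TP63 (chromosome 9, 14201848 to 14296035) 15 of 28 (adjusted exact p = 0.0123), and ROR1, a receptor for WNT5A, 11 of 17. RIPK4, a kinase of keratinocyte differentiation, had 10 of 15, FGFR3, a receptor for FGF ligands, 12 of 22, BPNT2 9 of 12, PTRHD1 11 of 19, PRMT3 9 of 14 and AGBL1 6 of 7. The 1170 regions open in cranial feather only lay within the crossed splits (330 to 2273), so the genes below are not shown to differ between the tissues. Regions open in cranial feather only were concentrated at TPCN1, an endolysosomal channel gene, with 6 of 17 (adjusted exact p = 6.18e-05), and at RPS27A with 4 of 7, the prohormone convertase gene PCSK2 with 4 of 8 and MYLPF, a myosin light chain gene of fast muscle, with 4 of 10. ABCA3, NAA10 and XCL1 followed with 3 regions each of 7, 9 and 9, and TBC1D12 with 3 of 11. In all, 15 genes passed for crest (353 unadjusted) and 36 for cranial feather (109 unadjusted), 8 of them with a symbol. With regions counted within 50 kb, 0 genes passed for crest and 23 for cranial feather, and with equal numbers of peaks 8 and 20. Without cranial feather replicate 2 the crest count was 2, and without crest replicate 1 it was 50.

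In the HOXC window, crest mesenchyme had 17 and 13 peaks and cranial feather mesenchyme had 0 in both libraries. Of all juvenile regions, 17.1% were open in crest only, and the random windows were matched in length but not in number of regions. In the HOXC window 7 of 21 juvenile regions were open in crest only, against a mean of 0.914 in random windows (adjusted p = 0.0134, permutation of windows), and 0 in cranial feather only. They lay at the promoters of HOXC10 (ENSGALG00000029393, 7585646 to 7586066) and HOXC9 (7601063 to 7601950), in an intron of HOXC8 (7610297 to 7610841), at the promoter and in an intron of an unnamed gene model (7621757 to 7623680 and 7624802 to 7625980), and between genes (7578852 to 7579690 and 7598737 to 7599751). A peak of crest replicate 1 (7587847 to 7588090, -log10 p of 3.72) overlapped the inserted sequence in HOXC10 (7587783 to 7587977) and ran past its end. No other juvenile library had a peak on the insertion. The crest peaks at the HOXC10 promoter had a -log10 p of 7.54 and 9.61. The insertion holds duplicated sequence, and reads of its copies may not be told apart. So neither that peak nor the lack of one can be assigned to the inserted copy. HOXD had 16 and 18 peaks in crest and 9 and 10 in cranial feather, HOXA 11 and 6 against 7 and 8, and HOXB 9 and 1 against 7 and 11, and no region call passed in these clusters. At equal numbers of peaks each crest library kept 5 HOXC peaks and 3 regions were open in crest only (adjusted permutation p = 0.109), and with stricter peaks there were also 3 (adjusted p = 0.273).

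Regions open in crest only and in cranial feather only overlapped the E9 lists in different shares, and part of these differences did not hold in other settings. The authors' deposited scalp list was overlapped by 6.43% of 12779 crest regions and 3.42% of 1169 cranial feather regions (odds ratio 1.94, adjusted p = 2.19e-05, two-sided Fisher's exact test). The authors' deposited back list was overlapped by 2.86% and 6.84% (odds ratio 0.400, adjusted p = 1.32e-10), and the tail list by 2.17% and 0.941% (odds ratio 2.33, adjusted p = 0.00344). E9 regions open in all 6 libraries had an odds ratio of 1.83 and regions open only in scalp 0.707 (adjusted exact p = 0.148), and 8.26% of regions open in both juvenile tissues overlapped the scalp list. The part of the scalp list open only in scalp had an odds ratio of 3.02 and the part closed only there 4.55 (adjusted exact p = 0.0338 and 0.0055). These comparisons use the regions open in cranial feather only, whose number lay within the crossed splits. Regions open in crest only were also wider, with a median of 695 bp against 467.5 bp for cranial feather only. An overlap of 1 bp counted and widths were not matched, so width can raise these odds ratios. Those of the back list (0.400) and of regions open only in scalp (0.707) went the other way. These p values compare the libraries at hand, since regions are not replicates. The odds ratio of the tail list was 1.04 at equal numbers of peaks (adjusted exact p = 0.872), and 1.14 and 1.09 without crest replicate 1 or 2. That of the back list was 0.956 without cranial feather replicate 1 (adjusted exact p = 0.638) and 1.14 without cranial feather replicate 2 (adjusted p = 0.141).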

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

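The tests of background depth, of epidermal promoters, of markers of minor cell types and of random windows at HOXC were chosen after the results were seen.

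Crest mesenchyme had 12785 regions open only there and cranial feather mesenchyme 1170, a ratio of 10.9. Lower sequencing depth of the cranial feather libraries stays open for replicate 1 alone, whose background tag density of 0.982 of the crest mean rests on an assumed fragment length (0.808 when not divided by it), while replicate 2, with 35128 peaks, showed no lower background by either measure (1.004 and 1.048). The smaller number of peaks listed for cranial feather stays open, since with equal numbers of peaks the ratio was 1.81 and it ran from 0.717 to 2.40 when 1 library was left out, a test tilted by its construction, as the group left with 1 library has the looser rule. Lower signal over background in the cranial feather libraries cannot be told apart from a tissue difference here, since promoter regions open in all 6 E9 libraries were open in 93.3 and 92.1% in crest and in 87.3 and 90.5% in cranial feather, a gap of 1.59 points against a difference of up to 3.21 points within a tissue. With equal numbers of peaks these shares were 88.8 and 87.3% in crest and 87.3 and 89.6% in cranial feather, without such a gap, and a difference between the tissues themselves stays open as untested.

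Epidermal keratinocyte markers had 2.47 times the random mean of regions open in crest only, among them 15 regions at TP63. The smaller number of cranial feather peaks is argued against, since the ratio was 2.95 with equal numbers of peaks (permutation p = 0.0002, the smallest possible). A loss of regions near markers of every minor cell type stays open. Here 0 of 6 such lists had a ratio of 1.5 or more with permutation p under 0.05, and the ratios ran from 0.417 to 1.58. That test has little power, since simulated lists enriched by 1.5 times in an E9 comparison reached p under 0.05 in 48.9% of tests. Epidermal cells in the crest libraries cannot be told apart from opening of these genes in crest mesenchyme, since the share of promoters open in crest only, 7 of 23 epidermal against 33 of 353 others (odds ratio 4.24), restates the same calls. Epidermal promoters were also open in E9 dermis, 10 and 15 of 23 in the back libraries, and the labels name no sort that would remove epidermal cells.

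Both crest libraries had HOXC peaks, 17 and 13, and both cranial feather libraries had 0. The smaller number of cranial feather peaks is argued against as the whole cause. With equal numbers of peaks 5 remained in each crest library, and each cranial feather library had 0. Of 291 random windows with 5 peaks in each crest library only 1, at HOXC itself, had 0 in both cranial feather libraries. These windows were matched in number of crest peaks, not in peak strength or promoter content, so they cannot exclude a loss of weaker peaks. With equal numbers of peaks the count of regions open in crest only fell to 3 (adjusted permutation p = 0.109). A loss of chromosome 33 signal in cranial feather is argued against, since the ratio of cranial feather to crest peaks there outside HOXC was 1.67 times that on the other chromosomes, while signal over background stays open, with the gap of 1.59 points given above. HOXC chromatin that is open in crest and closed in cranial feather mesenchyme may be the biological difference, as a hypothesis found and tested on the same 4 libraries.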

How the results depend on the processing

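Apart from settings that leave out a library, 143 values of the results that answer a comparison kept their direction and side of the threshold or stayed within 1.5 times, 34 counts moved further and 10 calls ended. The counts of regions closed in a single site, the gene counts, the stricter peaks for HOX clusters and the leave-out settings for lists, clusters and genes were added after seeing the data, as were the shares of regions in list tests. The causes were not tested except where the construction gives them. Stricter peaks and equal numbers of peaks remove peaks by construction, short windows around summits split wide regions, and a group left with 1 library has a looser rule. Motif tests and their alternatives were not run. The peak files set no depth, so a region without a peak is not shown to be closed.

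With peaks at a -log10 q of 5 or more, 5549 regions were open in scalp and not in back, 3204 in tail and not in back, 4708 in tail and not in scalp and 1801 only in tail, while 1849 were closed only in scalp and 879 closed only in back. The juvenile counts were 8093 for crest and 449 for cranial feather. HOXC peaks per library were 2 in scalp, 12.5 in back, 9 in tail and 5.5 in crest. The back list had 5 HOXB regions (adjusted permutation p = 0.167), and 3 HOXC regions were open in crest only (adjusted p = 0.273). With short windows around summits, 16387 were open in scalp and not in back, 10997 in tail and not in back, 13049 in scalp and not in tail and 8822 only in scalp, and 3597 were closed only in back.

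With equal numbers of peaks, 4901 regions were open in crest only and 2702 in cranial feather only, each crest library had 5 HOXC peaks, 3 HOXC regions were open in crest only (adjusted permutation p = 0.109), the WNT ratio was 1.84 (adjusted p = 0.0806), and the tail list odds ratio was 1.04 (adjusted p = 0.872). Genes past the threshold then numbered 0 for back over tail, 4 for scalp over tail, 5 for the back list, 8 for crest and 20 for cranial feather. With regions within 50 kb they numbered 1 for scalp over back, 0 for back over tail, 1 for scalp over tail, 0 only in scalp, 0 only in back, 0 for the back list, 0 for crest and 23 for cranial feather. Of the genes named, 8 kept their call within 50 kb and 27 did not, and 19 kept it and 19 did not at equal numbers of peaks.

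Fisher's exact test over regions passed 11 list tests in place of 4. In regions 1000 bp or more from a start, the ratio of HOX paralogs 5 to 8 closed only in scalp was 6.02 (adjusted permutation p = 0.173) and that of epidermal markers 2.09 (adjusted p = 0.063). Without flanks, 3 HOXA and 2 HOXC regions were closed only in scalp (adjusted permutation p = 0.0656 and 0.0576), and 2 HOXC regions were on the tail list (adjusted p = 0.137). A replicate block, pairing libraries of the same number, gave 8871 and 6987 for scalp and back and the main counts in the other comparisons too, which its construction fixes.

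With each library left out in turn, regions open in scalp and not in back ran from 11054 to 17462 and the reverse from 9291 to 16042, back over tail from 6104 to 12833 and the reverse from 8667 to 16151, and scalp over tail from 9759 to 16253 and the reverse from 10762 to 18282. Each count grew by over 1.5 times without either library of the group that was open. It also did so without back replicate 1 for scalp over back (13393) and tail over back (10802), and without tail replicate 2 for back over tail (8286) and scalp over tail (12070). Regions open only in scalp ran from 5839 to 11977, in back from 2826 to 9239 and in tail from 4076 to 10665, with the larger values without either library of the site and 3654 for back without tail replicate 2. Regions closed only in scalp ran from 3422 to 4655 (without scalp replicate 2), in back from 2264 to 4129 and in tail from 1419 to 2770. Those closed only in back were 4129 and 2667 without its own replicates 1 and 2 and 2993 without tail replicate 1. Those closed only in tail were 1730 and 2770 without its own replicates 1 and 2, 1667 and 2020 without back replicates 1 and 2, and 1566 without scalp replicate 1. Crest over cranial feather ran from 14380 to 25198, with 22167 and 25198 without crest replicate 1 and 2. The reverse ran from 1517 to 5752, with 3270 without crest replicate 1, and 5190 and 5752 without cranial feather replicate 1 and 2.

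With a library left out, the ratio of HOX paralogs 5 to 8 closed only in scalp ran from 5.09 to 6.56, and its call ended without back replicate 1 (5.35, adjusted permutation p = 0.054) and tail replicate 1 (5.09, adjusted p = 0.0864). On the scalp list paralogs 1 to 4 ran from 3.00 to 3.64 and paralogs 5 to 8 from 3.91 to 5.09. The WNT ratio ran from 1.52 to 1.66, and the epidermal ratio from 1.65 to 2.13, with the call ended without crest replicate 2 (1.65, adjusted permutation p = 0.0864). The list tests that passed numbered 4 to 10, with 10 without scalp replicate 1, and the cluster tests 11 to 15. HOXA regions closed only in scalp ran from 4 to 8 (8 without scalp replicate 1), and the call ended without either back library or either tail library (4 each, adjusted permutation p = 0.0528 to 0.113). HOXA had 16 to 18 regions on the scalp list and 9 to 12 on the tail list. HOXB had 15 to 25 regions open in back and not in scalp (25 and 23 without back replicate 1 and 2), 13 to 22 in tail and not in scalp (22 without tail replicate 2), 10 to 14 closed only in scalp (14 without scalp replicate 2), 8 to 10 on the back list and 21 to 25 on the scalp list. HOXC had 9 to 15 open in back and not in scalp (15 without back replicate 1), 7 to 10 in tail and not in scalp, 5 to 6 closed only in scalp, 11 to 13 on the scalp list, 7 to 9 on the tail list and 7 to 17 open in crest only (13 and 17 without crest replicate 1 and 2).

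The odds ratio of the scalp list ran from 1.38 to 3.62, the latter without cranial feather replicate 2. That of regions closed only in scalp ran from 1.82 to 3.56, with 1.82 and 2.07 without crest replicate 1 and 2 and 2.05 without cranial feather replicate 1. That of the back list ran from 0.325 to 1.14, with 0.956 (adjusted exact p = 0.638) without cranial feather replicate 1 and the opposite direction, 1.14 (adjusted p = 0.141), without cranial feather replicate 2. That of the tail list ran from 1.09 to 3.13, and its call ended without crest replicate 1 (1.14, adjusted exact p = 0.461) and crest replicate 2 (1.09, adjusted p = 0.760). Genes past the threshold ran from 3 to 16 for scalp over back (9 and 16 without scalp replicate 1 and 2), from 0 to 4 for back over tail (0 without either tail library, 4 without back replicate 1) and from 6 to 11 for scalp over tail (6 without scalp replicate 1 or tail replicate 2). They ran from 1 to 8 only in scalp (8 and 3 without back replicate 1 and 2, 2 and 4 without tail replicate 1 and 2, 5 without scalp replicate 1) and from 1 to 4 only in back (4 without back replicate 1). They ran from 3 to 8 for the back list (4 and 3 without scalp replicate 1 and 2, 5 and 4 without tail replicate 1 and 2) and from 0 to 3 for the tail list (0 and 1 without tail replicate 1 and 2, 1 without scalp replicate 2). For crest they ran from 2 to 50 (50 without crest replicate 1, 7 and 2 without cranial feather replicate 1 and 2) and for cranial feather from 9 to 72 (9 without crest replicate 1, 56 and 72 without cranial feather replicate 1 and 2).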

Other observations

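Some gene groups leaned between the E9 sites without passing the adjusted threshold, and their members were named after the values were seen. Endothelial markers had 2 regions open in scalp and not in tail against a mean of 11.8 in random gene lists (ratio 0.169, permutation p = 0.0034, adjusted p = 0.107), 1 at FLT1 and 1 at FLI1, and 1 region open only in scalp against 7.65 (adjusted p = 0.255). Retinoic acid genes had 40 regions on the authors' deposited scalp list against 21.1 (ratio 1.90, permutation p = 0.0022, adjusted p = 0.0792), with 7 each at CYP26B1, a retinoic acid degrading enzyme, and RXRA, a retinoid receptor. FGF and SHH pathway genes had 15 regions closed only in tail against 5.45 (ratio 2.75, permutation p = 0.002, adjusted p = 0.054, an added test), 3 of them at FGFR2 and 2 each at GLI2 and GLI3. Cartilage and bone markers had 1 region open in tail and not in back against 9.42 (ratio 0.106, permutation p = 0.0046, adjusted p = 0.121).

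Among the cranial neural crest and frontonasal regulators, regions open in crest only lay at OTX1 (15 of 24), MSX2 (12 of 27), TFAP2C (10 of 19) and LMX1B (6 of 11), members named after their values were seen, and the list as a whole had an adjusted p of 0.0588. With the share of regions called in place of their number the adjusted p was 0.0202, an alternative chosen after seeing the data. Regions open in both libraries of each juvenile tissue numbered 19280, and 29106 were open in all 6 E9 libraries.

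The following hypotheses and their tests were made after the results were seen. Crest feathers grow on the head, and the crest libraries had 17 and 13 HOXC peaks where the E9 scalp libraries had 5 and 6. Crest mesenchyme may therefore have opened regions that E9 back and tail dermis share and E9 scalp dermis lacks. Not every crest peak was missing in scalp, since that of crest replicate 2 at 7580282 to 7580827 overlapped peaks of both scalp libraries. Past the insertion, peaks of crest and scalp were not compared. E9 regions closed only in scalp were overlapped by 291 of the regions open in crest only (2.28%) and by 7 of those open in cranial feather only (0.599%), an odds ratio of 3.87 (p = 1.9e-05, two-sided Fisher's exact test, adjusted p = 0.000124). It was 2.25 with equal numbers of peaks, 1.82 and 2.07 without crest replicate 1 and 2, and 2.05 and 3.56 without cranial feather replicate 1 and 2. The regions open in crest only were wider (median 695 bp against 467.5 bp) and widths were not matched, so width may add to this odds ratio.

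A further hypothesis was that this excess is larger for regions closed only in scalp than for regions closed only in another E9 site. The odds ratio between regions closed only in scalp and those closed only in tail was 3.46 (p = 0.0451, two-sided Fisher's exact test), and against those closed only in back it was 9.73 (p = 3.66e-08). The contrast with tail rests on 7 and 5 regions open in cranial feather only, a set whose total number lay within the crossed splits. Both contrasts were run at the main setting alone. Regions open only in scalp had an odds ratio of 0.707 (adjusted exact p = 0.148), and regions open in all 6 E9 libraries 1.83. Against this contrast, the part of the authors' deposited scalp list open only in scalp had an odds ratio of 3.02 (adjusted exact p = 0.0338). The part of the tail list open only in tail was overlapped by 57 regions open in crest only and 0 open in cranial feather only (adjusted exact p = 0.0297), so the excess is not limited to regions closed in scalp. Both tests went the way of the hypotheses for these libraries, but the second rests on few cranial feather regions and does not settle its hypothesis. Regions are not replicates, the juvenile and E9 tissues differ in breed and age, and the smaller number of cranial feather peaks stays open.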
